A study of Mus musculus with 12 samples.

How the data were processed

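RNA was measured in whole tibialis anterior muscle of male C57BL/6 mice. Per the labels, mice were injected at 8 weeks of age with AAV:TET and an empty vector or, contralaterally, AAV:Dux, and 7 days later some received chow with 600 mg/kg doxycycline. The labels name 2 or 7 days of doxycycline and do not state which applies to these libraries. Libraries were made from 200 ng of RNA by poly-A selection with a TruSeq kit, per the labels. The 12 libraries form 4 groups of 3, empty vector and Dux vector on each chow, and no library was left out.

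The values are read counts per gene, which the authors made with bcl2fastq 2.17.1.14, STAR and featureCounts on GRCm38, per the submitters' processing notes. Versions of STAR and featureCounts and the gene annotation behind the counts are not given in the sources used here. The table as deposited holds 12752 genes with raw counts, and the lowest mean count of a gene over the libraries is 10.0, so genes below that level are not analysed here. Totals were 11880593 (DUX_DOX 3) to 13811999 (DUX 1) counts per library. All columns were mapped to their groups by name, 3 symbols had a pair of gene identifiers each, and the libraries of a group were checked for duplicates, with a chi-square per degree of freedom between pairs from 4.89 to 25.9. The Dux gene itself is not analysed here, and the transcript beside it, AW822073, was read in its place.

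Gene coordinates and types came from GENCODE release M21 on GRCm38, in which 12728 identifiers were found, 12076 of them protein-coding. Transcript length and GC content could be set for 12723 genes (99.8%). Reads of nearly identical genes, such as the Zscan4 and Usp17l families, could not be assigned to single members from the counts, so single values of these genes are uncertain.

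The test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM factors (0.916 to 1.12), the default filter on low counts over the 4 groups and 1 mean per group, fitted to all 12 libraries. It left 12751 genes. The median biological coefficient of variation was 12.3%, with 6.12 prior degrees of freedom. The contrasts were Dux against empty vector on each chow, doxycycline against normal chow in each vector, and the interaction of vector and chow. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Fold changes are log2 values with a prior count of 0.125, and their standard errors come from the fit. CPM are counts scaled to the TMM-adjusted library totals. The p-values measure the spread between libraries, since the labels do not state that the libraries of a group come from separate animals.

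A gene with 0 counts in a whole group was given a lower bound of its fold against a floor of 3 counts over the group. A gene with 1 to 3 counts was given the ratio with its 95% counting interval. Bounds and intervals cover counting error only, and fitted fold changes of such genes depend on the prior count.

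The tests, the alternatives and 32 gene lists, including markers of other cell types in whole muscle, were fixed before the data were examined. The lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the correlation between genes preset at 0.01, adjusted over the 30 lists with at least 3 members measured. Each list was tested again with the correlation estimated from the data and with fry, which asks whether the genes of a list move one way and compares no list with other genes. The Dux target list had 43 symbols, of which 18 were measured in 20 gene identifiers. The macrophage and tenocyte lists share 0 genes with the other lists.

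The genes named in the text were chosen by a rule. It took the transcript of the Dux locus in every library. It took genes past the threshold with at least 5 CPM in the higher group, no overlap between the groups compared and a symbol outside a set of name patterns for predicted or unnamed genes. The patterns were Gm with digits, an ending in Rik, 2 capitals with 6 digits, -ps, Mir, Snor and bare identifiers, and clone names of the form RP24-351P7.8 were not covered and could be picked. Of these the 6 largest rises and 6 largest falls were named for DUX_DOX against EV_DOX and against DUX, and 3 and 3 elsewhere. In DUX_DOX against EV_DOX it took the 3 members with the smallest p of the Dux target, myostatin-activin, atrophy and p53 lists and 2 of every other list past camera, and in other comparisons 1 member of each list past camera. Mstn, Acvr2b, Fst, Trim63 and Fbxo32 were named in each comparison. Some names were left out for length, and a few genes that the rule picked are not reported here.

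The steps were tested on simulated data with known changes, in 12752 genes with the depth and spread of the real libraries. The simulations changed 66 or 67 genes per fold, far fewer than the 3224 called for DUX_DOX against EV_DOX. For DUX_DOX against EV_DOX the test recovered 37.3% of the genes changed 1.5-fold, 76.1% of those changed 2-fold and 97.0% of those changed 4-fold. For the interaction the shares were 10.4%, 59.7% and 84.8%. False calls made up 4.11% of the calls in the former and 2.83% in the latter, and 7.23% for doxycycline in empty vector muscle. Camera called 1 of 1 planted lists and 0 of 20 unchanged lists. The simulated genes varied independently, so this does not test the preset correlation between genes.

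The alternatives fixed beforehand were DESeq2 size factors and upper-quartile factors in edgeR, no filter and a stricter filter (CPM above 1 in at least 3 libraries), the Wald test of DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a replicate block and leaving out each library in turn. Where a group was left with 2 libraries, the model pooled the spread over the groups. Offsets for GC content and for transcript length and a fit without EV 3 and EV_DOX 1 were added after the data were seen, as was camera without single libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the figures.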

Results

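Tibialis anterior muscles of male C57BL/6 mice received AAV:TET together with an empty vector or, in the contralateral limb, with AAV:Dux, and the mice were kept on normal chow or on doxycycline chow. Dux is the mouse homologue of human DUX4, the transcription factor misexpressed in facioscapulohumeral muscular dystrophy, and the series asks what Dux does to muscle and how this relates to myostatin and Smad signalling. The 4 groups of 3 RNA-seq libraries were empty vector on normal chow (EV), empty vector on doxycycline chow (EV_DOX), Dux vector on normal chow (DUX) and Dux vector on doxycycline chow (DUX_DOX). Levels are counts scaled to library size (CPM), given as mean and SD over the 3 libraries of a group. Fold changes are log2 estimates of the edgeR quasi-likelihood model with their standard errors (SE). Adjusted p-values are Benjamini-Hochberg values over the 12751 genes tested, and those of gene lists come from camera.

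The state of the Dux switch was read first from the transcript beside the Dux gene and from its target genes, since the Dux gene itself is not analysed here. Whether the reads of this transcript came from the vector or from the mouse locus was not tested. AW822073 (ENSMUSG00000058537) lies on chromosome 10 from 58222972 to 58224930 in GRCm38, beside Duxf3 at 58229979 to 58232675. It had 3.56 CPM (SD 0.74) in DUX_DOX, with 143 counts over the 3 libraries. It had 0 counts in EV, so that it was at least 45.5-fold higher in DUX_DOX. Against the 1 count in EV_DOX the ratio was 141, with a counting interval from 24.8 to 5594, and against the 3 counts in DUX it was 46.5 (15.6 to 228). Tmem92, a transmembrane protein gene in the list of Dux targets, had 4832 counts in DUX_DOX, 8 in DUX and 2 each in EV and EV_DOX. Over the 14 target genes below 1 CPM in the empty vector libraries, the counts were 15070 in DUX_DOX, 15 in DUX, 6 in EV_DOX and 2 in EV. This set of 14 was chosen after the counts were seen, among target genes called higher in DUX_DOX.

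**Figure D1:**
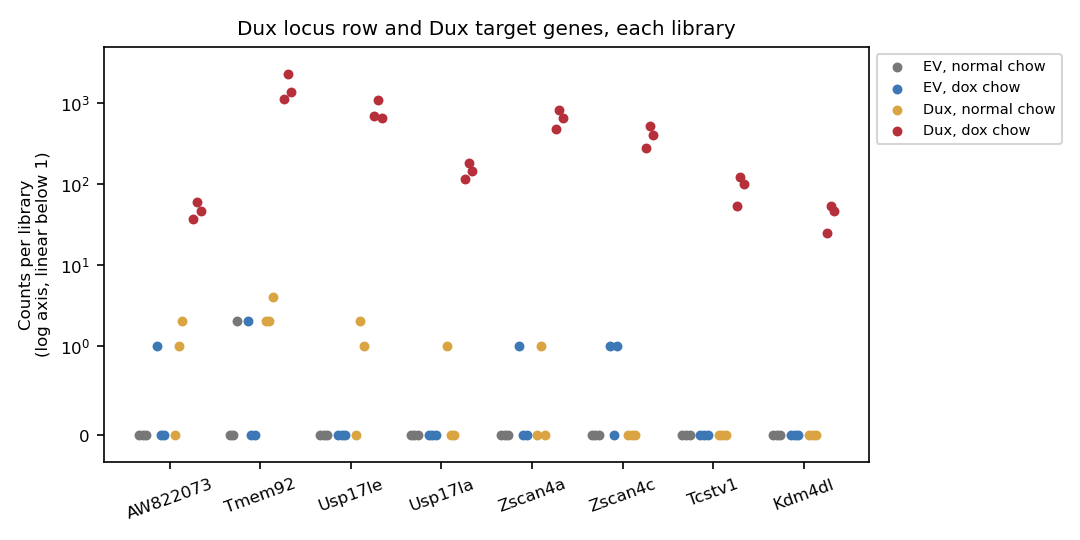
Counts per library (log axis, linear below 1) of the transcript beside the Dux gene and of 7 Dux target genes, 1 point per library and 3 libraries per group. Every DUX_DOX library lies above every library of the other 3 groups for each gene shown, for Tmem92 with 4832 counts against 12 in the other 9 libraries.

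The main comparison asked which genes Dux changed in induced muscle, DUX_DOX against EV_DOX. The largest rises included genes of the mouse 2-cell embryo and other members of the Dux target list that EV_DOX muscle hardly expressed. Usp17le, of a deubiquitinase family (chromosome 7, 104768049 to 104777470), reached 61.7 CPM (SD 15.4, n = 3) in DUX_DOX and had 0 counts in EV_DOX, at least 815-fold higher. Rfpl4b (chromosome 10, 38820541 to 38821779) reached 55.9 CPM (SD 17.8) and was at least 740.3-fold higher. Tmem92 (chromosome 11, 94777217 to 94782703) reached 119.6 CPM (SD 42.5), with a ratio of 2376 against 2 counts in EV_DOX and a counting interval from 657 to 19627. Zscan4a, of the Zscan4 zinc finger genes of the 2-cell embryo (chromosome 7, 10794242 to 10799057, typed as an unprocessed pseudogene in the reference annotation), had 1 count in EV_DOX and 48.9 CPM (SD 10.9) in DUX_DOX, a ratio of 1936 (347 to 76492). Zscan4d rose at least 250.5-fold and Zscan4f at least 229-fold from 0 counts. Values of single Zscan4 and Usp17l genes are uncertain because their members are nearly identical in sequence. Of the 20 members of the target list measured, 15 were higher and 2 lower, both over all genes and adjusted over the list alone. The lower members were Gabpb2 (log2 fold change -0.38) and Zfp750 (-2.26). The list median was 9.80 by the fitted values and 7.27 with genes at 0 counts set to their bound. The list passed camera at adjusted p = 1.42e-18, and adjusted p = 0.0575 with an estimated correlation. Of 43 symbols of the list 18 were measured, and genes with a mean count below 10.0 are not analysed here. Members with hardly any counts outside DUX_DOX, such as Kdm4dl with 124 counts in DUX_DOX and 0 elsewhere, entered only because DUX_DOX was high. Their rise was fixed in advance, so the counts, medians and camera values of this list are no separate evidence of induction.

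Many stress response genes rose with them in DUX_DOX. So did Gm26917, a noncoding transcript named outside the rule, by 4.16 (SE 0.25, adjusted p = 4.82e-08), with 0.00348% to 0.00693% of the counts in DUX_DOX libraries and 0.000152% to 0.000298% in the other 9. Whether its rise marked a difference in RNA quality or an effect of Dux was not tested. Hspb1, a small heat shock protein of muscle (chromosome 5, 135887919 to 135889563), went from 55.6 CPM (SD 3.21) to 1145 CPM (SD 92.3), a log2 fold change of 4.36 (SE 0.12, adjusted p = 1.76e-11). Hspa1a, an inducible heat shock chaperone, rose from 1.35 CPM (SD 0.316) to 208.6 CPM (SD 81.6). In the heat shock and oxidative stress list 14 of 24 genes rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 1.01 and camera adjusted p = 2.39e-08. Atf3, a stress-induced transcription factor, rose by 6.28 (SE 0.29, adjusted p = 3.62e-09) to 201 CPM (SD 13.5). Ppp1r15a, the phosphatase subunit that reverses the integrated stress response, rose by 2.76 (SE 0.12, adjusted p = 2.57e-09). Of the 28 genes of the integrated stress and unfolded protein response list, 17 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 0.75. Its camera adjusted p was 1.60e-08, and adjusted p = 0.0575 with an estimated correlation. Btg2, an antiproliferative p53 target, rose by 2.26 (SE 0.11, adjusted p = 7.14e-09) and Pmaip1, which encodes the death factor Noxa, by 4.43 (SE 0.48). Of the 38 p53 response and cell death genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.41 and camera adjusted p = 2.99e-05. Of the 13 lists that passed camera in this comparison, the calls of the p53 list (adjusted p = 0.0247) and of the heat shock list (adjusted p = 0.0406) held with an estimated correlation.

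Most macrophage markers and a part of the chemokine, matrix and cell cycle genes were higher in DUX_DOX as well. Cd68, a lysosomal protein of macrophages, rose from 4.54 CPM (SD 0.408) to 31.3 CPM (SD 6.4), a log2 fold change of 2.78 (SE 0.23, adjusted p = 1.26e-06), and Itgam, the alpha chain of a myeloid integrin, rose by 2.37 (SE 0.30). Of 24 macrophage and monocyte markers 20 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 1.21 and camera adjusted p = 1.49e-08, and adjusted p = 0.310 with an estimated correlation. The chemokine genes Ccl7 and Ccl6 rose by 5.24 (SE 0.43) and 2.11 (SE 0.18). In the cytokine and chemokine list 6 of 13 genes rose (6 adjusted over the list alone), with a median of 0.52 and camera adjusted p = 0.000634, and adjusted p = 0.141 with an estimated correlation. Timp1, an inhibitor of metalloproteinases, rose by 4.67 (SE 0.34). Of 35 matrix and fibrosis genes 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.55 and camera adjusted p = 0.000402, and adjusted p = 0.925 with an estimated correlation. The matrix median was 0.80 without EV_DOX 1 (camera adjusted p = 3.68e-07) and 0.25 without EV_DOX 3, where the call was lost (camera adjusted p = 0.0638). Col1a1 stood at 1609 CPM in EV_DOX 1 against 527 and 211 CPM in EV_DOX 2 and EV_DOX 3, and the tenocyte markers had a median of -1.24, or 0.43 without EV_DOX 1. Pcna, the sliding clamp of DNA replication, rose by 1.06 (SE 0.11) and Mcm6, a subunit of the replicative helicase, by 1.30 (SE 0.20). Of 28 cell cycle genes 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.89 and camera adjusted p = 5.01e-06, and adjusted p = 0.157 with an estimated correlation.

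**Figure D2:**
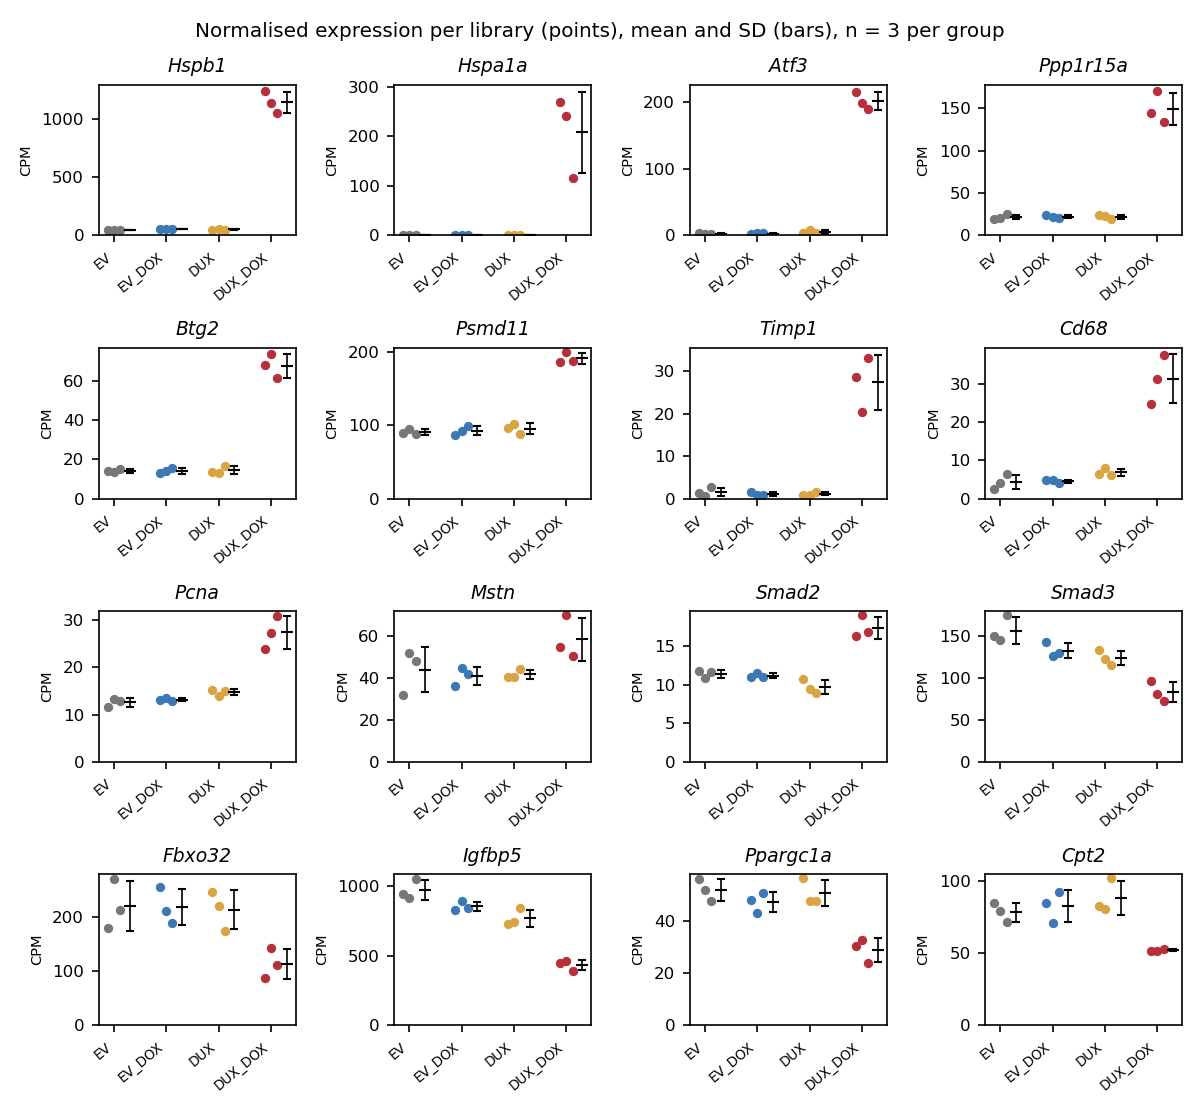
CPM of 16 named genes in each library (points) with group mean and SD (bars), n = 3 libraries per group. Hspb1 averaged 1145 CPM in DUX_DOX against 55.6 in EV_DOX, and Fbxo32 113.6 against 218.2 CPM.

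Some fibre metabolism and fast fibre genes were lower in DUX_DOX. Ppargc1a, a coactivator of mitochondrial biogenesis, fell by 0.71 (SE 0.12, adjusted p = 0.000590) and Cpt2, which imports fatty acids into oxidation, by 0.67 (SE 0.11). Of 36 fatty acid oxidation and TCA cycle genes 15 fell and 0 rose (24 and 1 adjusted over the list alone), with a median of -0.34 and camera adjusted p = 1.64e-07, and adjusted p = 0.522 with an estimated correlation. Phkg1, the catalytic subunit of muscle phosphorylase kinase, fell from 515.8 CPM (SD 22.7) to 319.2 CPM (SD 19.4). In the glycolysis and glycogen list 13 of 30 genes fell and 1 rose (19 and 2 adjusted over the list alone), with a median of -0.32 and camera adjusted p = 1.57e-06, and adjusted p = 0.508 with an estimated correlation. Trdn, which anchors the calcium release complex, fell by 0.54 (SE 0.10) and Cacnb1, a calcium channel subunit, by 0.56 (SE 0.11). Of 25 fast-twitch contractile and calcium handling genes 10 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.28 and camera adjusted p = 8.41e-07, and adjusted p = 0.214 with an estimated correlation. Ndufs1 and Sdha, subunits of respiratory complexes, fell by 0.42 (SE 0.10) and 0.38 (SE 0.09). They were among the 4 of 57 oxidative phosphorylation genes that fell, with 0 that rose (2 and 0 adjusted over the list alone), a median of -0.18, camera adjusted p = 0.000307, and adjusted p = 0.925 with an estimated correlation. This list call was lost without DUX_DOX 2 (adjusted p = 0.0658) or EV_DOX 3 (0.175), and that of the adipocyte markers in 4 of the 12 fits that left out 1 library, up to adjusted p = 0.0776. Plin4, a lipid droplet protein, fell by 0.77 (SE 0.12), the 1 called gene of 8 adipocyte markers (1 adjusted over the list alone), whose median was -0.55 with camera adjusted p = 0.0298, and adjusted p = 0.522 with an estimated correlation. Dgat2, a triglyceride synthesis enzyme of that list, had a log2 fold change of -0.35 (adjusted p = 0.0806), and without EV_DOX 2 of -0.49 (adjusted p = 0.0256), a call also made with the GC content offset (0.0432) and the transcript length offset (0.0431), in a range from 0.0256 to 0.305 over all alternatives. Beside these falls, the summed level of the macrophage markers was 191 CPM (SD 32.4) in EV_DOX and 436 CPM (SD 94.8) in DUX_DOX.

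The myostatin and atrophy genes, the focus of the series, moved in both directions in DUX_DOX. Smad2 rose by 0.64 (SE 0.11, adjusted p = 0.000569) and Tgfb1 by 0.76 (SE 0.13), whereas Smad3 fell by 0.67 (SE 0.11, adjusted p = 0.000513). Mstn, which encodes myostatin (chromosome 1, 53061640 to 53068079), rose by 0.51 (SE 0.16, adjusted p = 0.0296), from 40.8 CPM (SD 4.35) to 58.2 CPM (SD 10.3). The Mstn call was lost without DUX_DOX 2 (0.35, adjusted p = 0.151), without EV_DOX 1 (adjusted p = 0.0857) and without EV_DOX 3 (adjusted p = 0.0585), in a range from 0.00712 to 0.151 over all alternatives. Acvr2b, the receptor of myostatin, had a log2 fold change of -1.05 (SE 0.38, adjusted p = 0.0591), and passed in the DESeq2 Wald test (adjusted p = 0.0339), without DUX_DOX 2 (adjusted p = 0.0280) and without EV_DOX 2 (adjusted p = 0.0207), in a range from 0.0207 to 0.316. Fst, which encodes the myostatin antagonist follistatin, had a log2 fold change of 0.14 (adjusted p = 0.809). In the myostatin-activin list 7 of 30 genes rose and 3 fell (8 and 4 adjusted over the list alone), with a median of 0.10 and camera adjusted p = 0.657. Of the muscle ubiquitin ligase genes, Fbxo32 (chromosome 15, 58175879 to 58214932) fell by 0.94 (SE 0.19, adjusted p = 0.00233), from 218.2 CPM (SD 33.5) to 113.6 CPM (SD 27.4), and Trim63 had a log2 fold change of -0.07 (adjusted p = 0.741). Psmd11, a proteasome subunit, rose by 1.05 (SE 0.08) and Gabarapl1, an autophagosome protein, by 0.69 (SE 0.10), whereas Igfbp5, a binding protein of insulin-like growth factors, fell by 0.99 (SE 0.10). Of the 39 atrophy, ubiquitin ligase and autophagy genes 10 rose and 10 fell (10 and 10 adjusted over the list alone), with a camera adjusted p of 0.869.

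The largest falls were in Zfp871, a zinc finger gene (-2.04, SE 0.43), Npr3, the natriuretic peptide clearance receptor (-1.87, SE 0.59, adjusted p = 0.0309), Slc25a34, a mitochondrial carrier (-1.74, SE 0.38), Papln, a matrix glycoprotein (-1.55, SE 0.42, adjusted p = 0.0154), Cyp4f39, a cytochrome P450 gene (-1.42, SE 0.34), and Klhl33 (-1.35, SE 0.16). Npr3 was not called without EV_DOX 1 (-0.57, adjusted p = 0.303), DUX_DOX 1 (0.0535), DUX_DOX 2 (0.0943) or DUX_DOX 3 (0.102), in limma-voom (0.136) or with only the groups compared (0.0523), in a range from 0.0106 to 0.303 over all alternatives. Papln was not called without DUX_DOX 2 (0.0503), DUX_DOX 3 (0.0539) or EV_DOX 1 (0.0768), in a range from 0.000861 to 0.0847. In all, 3224 genes passed the test in DUX_DOX against EV_DOX, 1905 higher and 1319 lower, of which 618 and 87 changed by more than 2-fold. Without DUX_DOX 3 the count was 2109. The balance depended on the scaling, with 59.1% of calls higher here and 50.9% (1709 higher and 1647 lower) with upper-quartile factors.

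The other fixed lists did not pass camera in this comparison with all libraries, although single members moved. Higher and lower genes numbered 10 and 12 of 32 in the sarcomere scaffold and dystrophin list (10 and 14 adjusted over the list alone; adjusted p = 0.688), 2 and 1 of 15 slow-twitch genes (0.804) and 6 and 3 of 29 myogenic regulators (0.874). They numbered 4 and 2 of 16 denervation-responsive genes (4 and 4 adjusted over the list alone; 0.688), 0 and 1 of 9 mitochondrially encoded genes (0.307), 2 and 0 of 38 interferon genes (0 and 0 adjusted over the list alone; 0.453) and 4 and 0 of 24 antigen presentation genes (3 and 0 adjusted over the list alone; 0.106). Among cell type markers they numbered 0 and 1 of 3 T and NK cell genes (0.547), 3 and 1 of 17 endothelial (2 and 1 adjusted over the list alone; 0.663), 3 and 0 of 15 fibro-adipogenic (0.311), 1 and 1 of 10 smooth muscle (3 and 1 adjusted over the list alone; 0.813), 2 and 1 of 13 satellite cell (0.869) and 1 and 0 of 10 Schwann cell markers (0.159). None of the 5 red blood cell markers (adjusted p = 0.452) and none of the 8 tenocyte markers (median -1.24, adjusted p = 0.564) passed the test in edgeR, and the tenocyte median was 0.43 without EV_DOX 1 (adjusted p = 0.589). The B and plasma cell list (0 higher and 1 lower of 2) and the neutrophil list (1 and 0 of 2) had too few members for camera. Without EV_DOX 2 the Schwann cell median went from 0.22 to 0.78, with 6 markers higher and camera adjusted p = 0.000271. The fibro-adipogenic list passed in that fit too (0.0269). Antigen presentation passed without DUX 3 (0.0492), DUX_DOX 2 (0.0416) or EV_DOX 1 (0.0453), and mitochondrially encoded genes, downwards, without EV_DOX 1 (0.0440). The median, the mean and the camera direction differed in sign for the atrophy, slow-twitch, sarcomere, myogenic and endothelial lists.

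**Figure D3:**
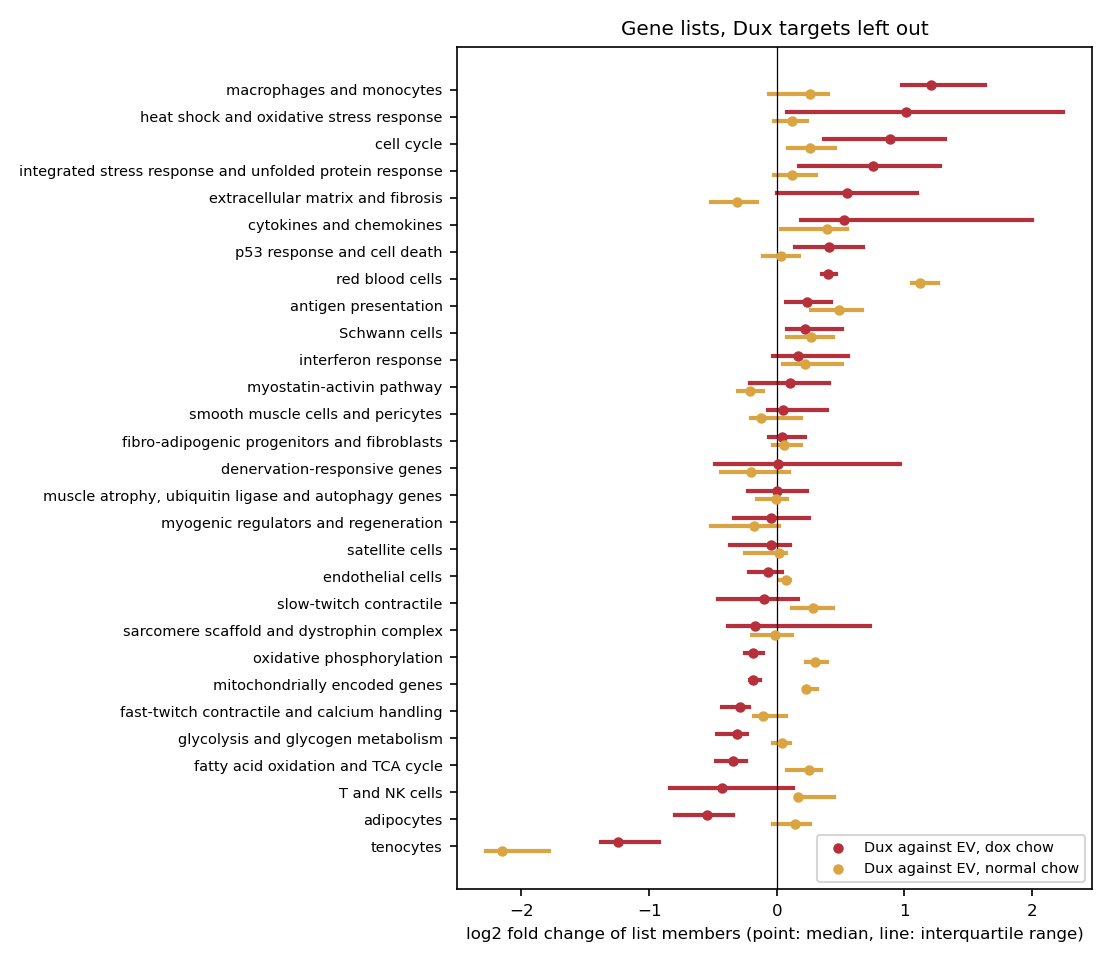
Median (points) and interquartile range (lines) of the log2 fold changes of the members of each fixed list, for Dux against empty vector on doxycycline chow and on normal chow, the Dux target list left out. The macrophage median was 1.21 on doxycycline chow and 0.26 on normal chow, and the tenocyte median -1.24 (0.43 without EV_DOX 1) and -2.15 (-0.93 without EV 3).

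The second comparison asked whether the Dux vector changed muscle without doxycycline, DUX against EV. No gene passed in edgeR, with a smallest adjusted p of 0.179. At an unadjusted p under 0.05 there were 2012 genes, limma-voom called 0 and the DESeq2 Wald test called 115, 51 higher and 64 lower. Without EV 2 the edgeR count was 118 and without DUX 2 it was 1. Of the named genes, Cox5b, a cytochrome oxidase subunit, had a log2 fold change of 0.57 (SE 0.12, adjusted p = 0.179), Psme1, an immunoproteasome activator, of 0.79 (SE 0.19, adjusted p = 0.192) and Gdf11, a ligand closely related to myostatin, of -1.68 (SE 0.42, adjusted p = 0.192). Without EV 2, adjusted p was 0.0224 for Psme1, 0.0224 for Gdf11, 0.0374 for Atf5, a stress response factor, and 0.0430 for Myoz2, a slow fibre protein. The DESeq2 Wald test called Cox5b (0.00345), Psme1 (0.0113), Atf5 (0.0267) and Gdf11 (0.0493). Over all alternatives adjusted p ranged from 0.00345 to 0.503 for Cox5b, from 0.0113 to 0.503 for Psme1, from 0.0224 to 0.503 for Gdf11, from 0.0267 to 0.503 for Atf5 and from 0.0430 to 0.562 for Myoz2. Mstn (-0.07, adjusted p = 0.858), Acvr2b (-0.80, 0.289), Fst (-0.46, 0.541), Trim63 (-0.01, 0.984) and Fbxo32 (-0.05, 0.922) did not pass.

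Lists of genes nevertheless leaned one way in DUX against EV, with 14 past camera and 0 of them with an estimated correlation. The 57 oxidative phosphorylation genes all had positive log2 fold changes, with a median of 0.30 (camera adjusted p = 5.38e-15, and adjusted p = 0.490 with an estimated correlation), and 9 of them passed when adjusted over the list alone, against 0 over all genes. Positive medians with the same adjusted p of 0.490 with an estimated correlation were found for antigen presentation (0.49, camera adjusted p = 1.07e-07, 6 of 24 genes adjusted over the list alone), fatty acid oxidation (0.25, 7.07e-07, 3 of 36), mitochondrially encoded genes (0.23, 0.00128, 1 of 9), red blood cell markers (1.12, 0.000875, 5 of 5), cytokines (0.40, 0.0174, 2 of 13), cell cycle (0.26, 0.0174) and the integrated stress response (0.12, 0.0290, 1 of 28). Slow-twitch genes had a median of 0.28 (camera adjusted p = 0.0371, and adjusted p = 0.504 with an estimated correlation) and macrophage markers of 0.26 (0.0290, and adjusted p = 0.685 with an estimated correlation). Negative medians were found for tenocyte markers (-2.15, camera adjusted p = 0.000770, 7 of 8 genes lower adjusted over the list alone), the myostatin-activin list (-0.21, 0.00102, 2 of 30) and myogenic regulators (-0.18, 0.0174), each with adjusted p = 0.490 with an estimated correlation. The matrix list had a median of -0.31 (0.0174, and adjusted p = 0.685 with an estimated correlation). The Dux target list did not pass (adjusted p = 0.0994), and the median, the mean and the camera direction differed in sign for the sarcomere and satellite cell lists, which did not pass. These leanings stood beside differences in traits of the libraries. Fmod, a tendon proteoglycan, stood at 540 CPM in EV 3 and 499.6 CPM in EV_DOX 1 against 36.8 to 121 CPM in the other 10 libraries. Gbp10, an interferon-induced gene, stood at 8.78 CPM in DUX 1, 11.3 in DUX 2 and 9.54 in EV 2. In DUX 3, EV 1 and EV 3 it stood at 0.69 to 2.32 CPM. The interferon list did not pass camera (adjusted p = 0.0566), but passed upwards without DUX 3 (1.78e-08) or EV 2 (0.000504). Antigen presentation passed in 12 of 12 fits that left out a library, with adjusted p up to 0.000133. Whether its rise followed the libraries high in Gbp10 or the Dux vector was not tested. Across genes, which are not independent replicates, the fold change had a Spearman rho of -0.430 with transcript length. With a transcript length offset, chosen after the data were seen, 8 of the 14 lists remained past camera. Among these were oxidative phosphorylation (adjusted p = 1.85e-08) and antigen presentation (1.23e-06). The slow-twitch, myogenic, integrated stress, matrix, cytokine, cell cycle and macrophage lists were each lost in at least 1 of the 12 fits that left out a library, and without EV 3 the tenocyte median was -0.93 (camera adjusted p = 0.0184).

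**Figure D4:**
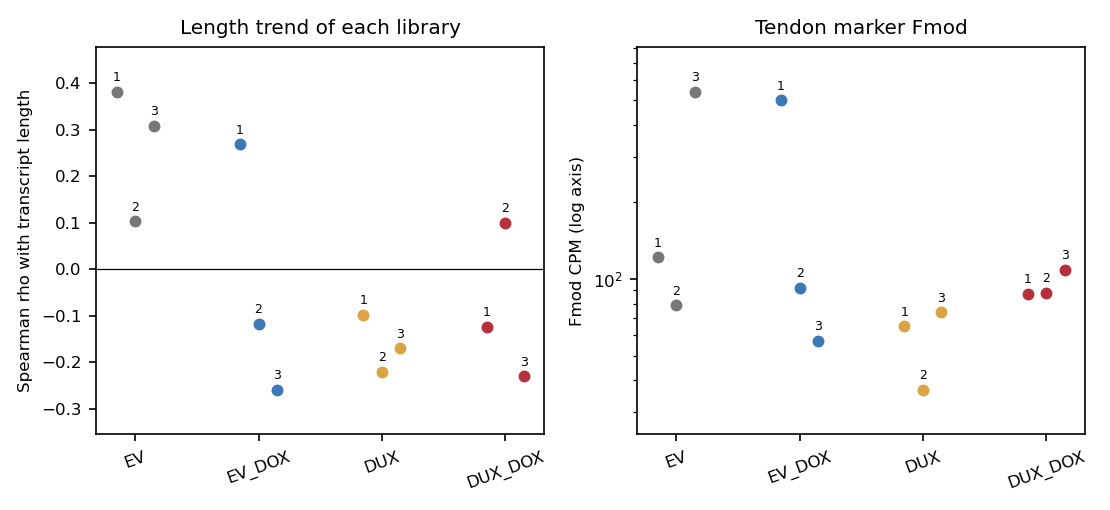
Spearman rho across genes, for each library, of the log2 level relative to the gene's mean over libraries with transcript length (left) and Fmod level in CPM on a log axis (right), 1 point per library numbered by replicate. Fmod was 540 CPM in EV 3 and 499.6 CPM in EV_DOX 1, and at most 121 CPM in the other 10 libraries.

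The third comparison was the control for doxycycline itself, EV_DOX against EV. In it 5 genes passed, all higher, with 999 at an unadjusted p under 0.05. Scand1, a SCAN domain gene, rose by 1.62 (SE 0.21, adjusted p = 0.0284), from 3.22 CPM (SD 0.886) to 9.91 CPM (SD 2.53). Phospho1, a phosphatase of mineralising tissue, rose by 1.30 (SE 0.20, adjusted p = 0.0465) and Ccdc85b by 1.19 (SE 0.19, adjusted p = 0.0465). The other called genes, Mafa (0.99, SE 0.15) and Bmyc (0.98, SE 0.15), were named after their values were seen. The calls depended on the libraries and settings. The count was 10 without EV_DOX 1, 2 without EV 1, 2 without DUX_DOX 2, 1 without EV_DOX 2 and 0 without DUX 1, DUX 2, DUX 3, DUX_DOX 1, DUX_DOX 3, EV 2, EV 3 or EV_DOX 3. It was 12 with DESeq2, 0 with limma-voom, 0 with only the groups compared and 0 without EV 3 and EV_DOX 1 together. Scand1, Phospho1 and Ccdc85b passed in 4, 1 and 2 of the 12 fits that each left out 1 library. Mstn (-0.10, adjusted p = 0.907), Acvr2b (-0.48, 0.739), Fst (-0.38, 0.814), Trim63 (0.10, 0.894) and Fbxo32 (-0.02, 0.992) did not pass.

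In all, 5 lists passed camera for doxycycline in empty vector muscle, each with adjusted p = 0.946 with an estimated correlation. Medians were positive for slow-twitch (0.43, camera adjusted p = 0.0229), oxidative phosphorylation (0.10, 0.0457) and antigen presentation genes (0.16, 0.0457), and negative for interferon (-0.40, 0.0188) and sarcomere genes (-0.13, 0.0188). In edgeR 0 members of these lists were called, over all genes or adjusted over the list alone. The median, the mean and the camera direction differed in sign for the fast-twitch, cytokine, red blood cell, fibro-adipogenic and Schwann cell lists, none of which passed. Myl2, the slow fibre myosin light chain, had a log2 fold change of 3.53 (SE 1.02, adjusted p = 0.463), with 35.2 CPM in EV_DOX 2 against 0.921 to 3.6 CPM in the other 5 libraries of the comparison. Across genes the fold change had a Spearman rho of -0.378 with transcript length, and 2 of the 5 lists, slow-twitch and interferon, remained past camera with a length offset. With each library left out in turn, slow-twitch passed in 9, sarcomere in 10, interferon in 11, and oxidative phosphorylation and antigen presentation each in 6 of the 12 fits.

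The fourth comparison asked what doxycycline changed in muscle that carried the Dux vector, DUX_DOX against DUX. Many Dux targets, heat shock, integrated stress and p53 genes were higher and many metabolic genes lower, as against EV_DOX, and Gm26917 rose by 4.18 (SE 0.25). Zscan4c rose from 0 counts to 30.2 CPM (SD 7.98), at least 394-fold, Zscan4d at least 248-fold and Zscan4f at least 227-fold. Zscan4a had a ratio of 1918 (344 to 75791), and Tmem92 rose by 9.12 (SE 0.39, adjusted p = 2.09e-09). In the target list 15 of 20 genes rose and 2 fell (15 and 3 adjusted over the list alone), with a median of 8.87, or 7.37 with genes at 0 counts set to their bound (camera adjusted p = 5.35e-16, and adjusted p = 0.0932 with an estimated correlation). Again, members with hardly any counts outside DUX_DOX were measured only because DUX_DOX was high. Hspb1 rose by 4.48 (SE 0.12, adjusted p = 1.33e-11) with 16 heat shock genes up and 2 down of 24 (16 and 3 adjusted over the list alone; camera 9.26e-08, and adjusted p = 0.0528 with an estimated correlation). Ppp1r15a rose by 2.78 (SE 0.12) with 18 integrated stress genes up and 1 down of 28 (18 and 1 adjusted over the list alone; camera 8.66e-07, and adjusted p = 0.117 with an estimated correlation). Btg2 rose by 2.23 (SE 0.11) with 18 p53 genes up and 1 down of 38 (19 and 2 adjusted over the list alone), the 1 list of 14 past camera (4.48e-05) that held with an estimated correlation (0.0281).

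Most macrophage markers and a part of the chemokine, matrix and cell cycle genes also rose on doxycycline in Dux muscle. Ccl2, a monocyte chemoattractant, rose by 4.23 (SE 0.44), with 6 of 13 cytokines up and 1 down (6 and 1 adjusted over the list alone; camera adjusted p = 0.00886, and adjusted p = 0.301 with an estimated correlation). Cd68 rose by 2.18 (SE 0.22), with 16 of 24 macrophage markers up and 0 down (19 and 0 adjusted over the list alone; camera 7.27e-06, and adjusted p = 0.434 with an estimated correlation). Of 35 matrix genes 15 rose and 0 fell (15 and 0 adjusted over the list alone; camera 4.48e-05, and adjusted p = 0.708 with an estimated correlation). The 8 tenocyte markers all had positive log2 fold changes, with a median of 0.64, but 0 were called and the list did not pass (adjusted p = 0.392). Pcna rose by 0.89 (SE 0.11), with 16 of 28 cell cycle genes up and 1 down (18 and 1 adjusted over the list alone; camera 4.99e-05, and adjusted p = 0.293 with an estimated correlation). Hadh, an enzyme of fatty acid oxidation, fell by 0.74 (SE 0.11), with 32 of 36 members of its list down and 0 up (34 and 0 adjusted over the list alone; camera 3.38e-13, and adjusted p = 0.302 with an estimated correlation). Ndufs1 fell by 0.61 (SE 0.10), with 35 of 57 oxidative phosphorylation genes down and 0 up (42 and 0 adjusted over the list alone; camera 2.38e-11, and adjusted p = 0.555 with an estimated correlation). The median of this list was -0.41 here, but -0.18 in DUX_DOX against EV_DOX and 0.30 in DUX against EV. Of the mitochondrially encoded genes 5 of 9 fell, among them mt-Nd6 by 0.72 (7 adjusted over the list alone; camera 0.00557, and adjusted p = 0.555 with an estimated correlation). Phkg1 fell by 0.59 with 22 of 30 glycolysis genes down and 1 up (25 and 2 adjusted over the list alone; camera 1.38e-08, and adjusted p = 0.321 with an estimated correlation), and Trdn fell by 0.44 with 6 of 25 fast-twitch genes down and 0 up (4 and 0 adjusted over the list alone; camera 0.000104, and adjusted p = 0.321 with an estimated correlation). Plin4 fell by 1.01, with 6 of 8 adipocyte markers down (7 adjusted over the list alone; camera 0.000708, and adjusted p = 0.302 with an estimated correlation). The median, the mean and the camera direction differed in sign for the sarcomere, denervation, antigen presentation and smooth muscle lists, which did not pass.

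Among genes that met the naming rule, the largest falls in DUX_DOX against DUX were Gbp10 (-2.85, SE 0.84, adjusted p = 0.0198) and Gbp6 (-2.41, SE 0.67, adjusted p = 0.0151), interferon-induced guanylate-binding proteins, Slc25a34 (-2.39, SE 0.38), Slc15a5 (-1.77), Aqp4, the water channel of fast fibres (-1.75, SE 0.11, adjusted p = 1.17e-07), and Mettl21e (-1.67). Gbp10 was not called without DUX 1 (0.0558), DUX 2 (0.0784), DUX_DOX 2 (0.0683) or DUX_DOX 3 (0.0787), in a range from 0.000564 to 0.0787, and Gbp6 was not called without DUX 2 (0.0725) or DUX_DOX 3 (0.0641), in a range from 0.00116 to 0.0725. With all libraries, interferon genes, 1 higher and 6 lower of 38 (1 and 2 adjusted over the list alone), did not pass as a list (camera adjusted p = 0.0845). Antigen presentation genes, 0 and 2 of 24 (0 and 0 adjusted over the list alone), did not pass either (0.741). Without DUX 3 the interferon list had 0 higher and 13 lower, a median of -0.49 against -0.25, and camera adjusted p = 3.48e-05. It also passed without DUX_DOX 2 (0.0192) or EV 2 (0.0488). Gbp10 stood at 8.78 CPM in DUX 1, 11.3 in DUX 2 and 9.54 in EV 2, which carries no Dux. In the other libraries, DUX 3 among them, it stood at 0.584 to 2.32 CPM. The fall of Gbp10 thus rested on high levels in DUX 1 and DUX 2, and DUX_DOX was not below all empty vector libraries. Fbxo32 fell by 0.91 (SE 0.19, adjusted p = 0.00253). Mstn rose by 0.49 (SE 0.16, adjusted p = 0.0339), a call lost without DUX 1 (0.0972), DUX 2 (0.0952), DUX 3 (0.0589) or DUX_DOX 2 (0.176), in a range from 0.00457 to 0.176. Acvr2b (-0.73, 0.181), Fst (0.23, 0.676) and Trim63 (0.03, 0.882) did not pass. In all, 3772 genes passed, 2101 higher and 1671 lower, with 594 and 152 beyond 2-fold, and with upper-quartile factors 1947 were higher and 1874 lower.

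The interaction asked whether the Dux effect differed between the chows. It passed for 1326 genes, of which 889 had a more positive Dux effect on doxycycline chow and 437 a more negative one. The Dux effect on Hspb1 was larger on doxycycline chow by 4.22 (SE 0.15, adjusted p = 1.24e-09), on Ppp1r15a by 2.75 (SE 0.17), on Btg2 by 2.23 (SE 0.16), on Cd68 by 2.12 (SE 0.35), on Ccl2 by 5.20 (SE 0.91), on Pcna by 0.83 (SE 0.15) and on Smad2 by 0.88 (SE 0.15, adjusted p = 0.00256). More negative effects on doxycycline chow were those on Slc25a34 (-2.70, SE 0.51), Plin5, a lipid droplet protein (-1.81, SE 0.29), Ucp3, a mitochondrial carrier of muscle (-1.65, SE 0.38), mt-Nd6 (-1.16), Hadh (-0.82), Plin4 (-0.75), Cox5b (-0.68) and Phkg1 (-0.53). The Cox5b call was lost without EV 3 (adjusted p = 0.0533, in a range from 0.00115 to 0.0533). For Fbxo32 the interaction was -0.89 (SE 0.26, adjusted p = 0.0446, from 0.00766 to 0.109 over the alternatives), and it was not called without DUX 1 (0.109), DUX 2 (0.0899), DUX_DOX 1 (0.0791), DUX_DOX 3 (0.0878), EV 1 (0.100), EV 3 (0.0978), EV_DOX 1 (0.0582) or EV_DOX 2 (0.0589). For Mstn it was 0.58 (SE 0.23, adjusted p = 0.112), and without EV 1 it was 0.77 (adjusted p = 0.0201), in a range from 0.0201 to 0.279. Acvr2b (-0.25, 0.806), Fst (0.61, 0.482) and Trim63 (-0.07, 0.872) did not pass. Fosl1, a member of the AP-1 family, had 7.30 (SE 1.58, adjusted p = 0.010) and was lost without EV 3 (0.171, in a range from 0.000211 to 0.171), and Zfp750, an epidermal zinc finger gene, had -3.29 (SE 0.82, adjusted p = 0.0209) and was lost without DUX 1 (0.0524), DUX_DOX 2 (0.0679), DUX_DOX 3 (0.0559) or EV_DOX 3 (0.0683), in a range from 0.00326 to 0.0683. The count was 2148 without EV_DOX 1, 813 without EV 3, 841 without DUX_DOX 2, 851 without DUX 3, 861 without EV_DOX 3, 862 without DUX 1 and 881 without DUX 2, and with upper-quartile factors 56.9% of 1426 calls were more positive against 67.0% here.

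Of the lists, 15 passed camera for the interaction, and those of Dux targets (median 8.60, adjusted p = 8.07e-22), p53 (0.35, 0.000866) and heat shock genes (0.91, 1.20e-08) also with an estimated correlation, each at adjusted p = 0.0406. Interactions were more positive and more negative for 14 and 1 of 24 heat shock genes (16 and 2 adjusted over the list alone), 7 and 0 of 38 p53 genes (10 and 0), and 0 and 1 of 20 Dux targets (0 and 1), most of which had 0 counts in several groups. Such targets were measured only because DUX_DOX was high, so the camera value of the Dux target list is no separate evidence. Further positive medians were those of the integrated stress (0.68, 9.25e-07, 13 and 1 of 28 genes, and adjusted p = 0.114 with an estimated correlation) and matrix lists (0.78, 4.90e-06, 11 and 0 of 35, and adjusted p = 0.555 with an estimated correlation), and of the myostatin-activin list (0.31, 0.0309, 3 and 0 of 30, and adjusted p = 0.555 with an estimated correlation). The 8 tenocyte markers were all positive too, with a median of 0.83, but 0 were called and the list did not pass (adjusted p = 0.206), and the tenocyte median was -0.08 without EV 3 and 2.43 without EV_DOX 1 (adjusted p = 0.00519). Macrophage markers (0.90, 2.27e-06, 6 of 24), cytokines (0.54, 0.0278, 5 of 13) and cell cycle genes (0.67, 0.00293, 2 of 28) were positive too, each with adjusted p = 0.392 with an estimated correlation. Negative medians were those of oxidative phosphorylation (-0.51, 1.84e-13, 7 of 57 genes lower, and adjusted p = 0.428 with an estimated correlation) and mitochondrially encoded genes (-0.38, 0.00576, 1 of 9, and adjusted p = 0.477 with an estimated correlation). The median Dux effect on oxidative phosphorylation genes was -0.18 on doxycycline chow and 0.30 on normal chow. For mitochondrially encoded genes it was -0.18 and 0.23. In both lists the larger effect was thus the rise on normal chow. Fatty acid oxidation (-0.50, 5.06e-13, 15 of 36), glycolysis (-0.38, 9.53e-07, 5 of 30), fast-twitch (-0.32, 0.000229, 0 of 25 in edgeR) and adipocyte lists (-0.68, 0.00993, 2 of 8) were negative, each with adjusted p = 0.392 with an estimated correlation. Adjusted over the list alone, the counts were 15 and 1 for integrated stress, 14 and 0 for matrix, 16 for macrophage, 41 for oxidative phosphorylation, 31 for fatty acid oxidation and 16 for glycolysis genes, the last with 1 more positive. They were 4 for the myostatin-activin, 5 and 1 for the cytokine, 2 for the cell cycle, 1 for the mitochondrially encoded, 0 for the fast-twitch and 2 for the adipocyte list. The median, the mean and the camera direction differed in sign for the atrophy, sarcomere, denervation, interferon, fibro-adipogenic and satellite cell lists, which did not pass. With the transcript length offset 13 of the 15 lists remained past camera, without the myostatin-activin list (adjusted p = 0.0764) and the mitochondrially encoded genes (adjusted p = 0.0595). The myostatin-activin list was lost without EV 3 (0.134) or EV_DOX 3 (0.106), the cytokine list without DUX_DOX 3 (0.0664) and the adipocyte list without EV 2 (0.0575).

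The Dux effects on the pair of chows were also compared directly. Across 12751 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.244 and a Spearman rho of 0.139, and the pair of effects shared no library. Of the 3224 genes called on doxycycline chow, 1901 (59.0%) had the same sign on normal chow. The share over all 12751 genes was not computed, so 59.0% cannot be read as particular to the called genes. Without EV_DOX 1 the Pearson r was 0.129.

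**Figure D5:**
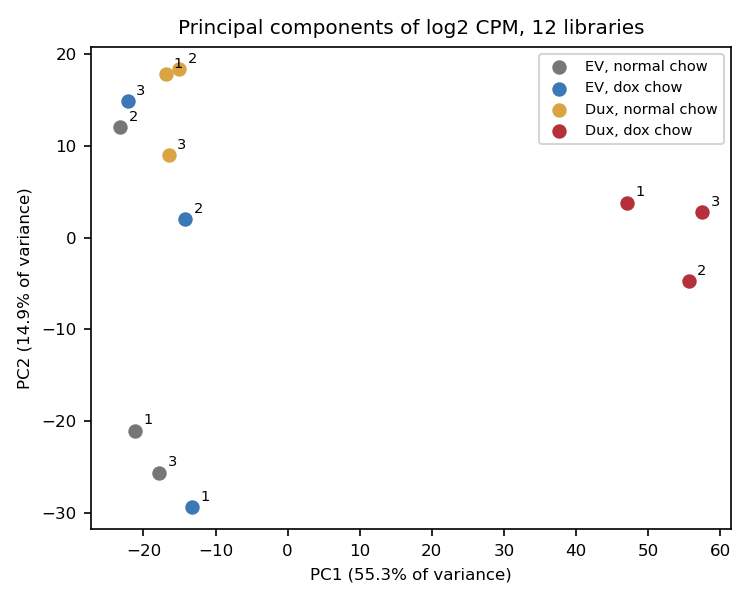
Principal components of log2 CPM of the 12 libraries, numbered by replicate, with the percentage of variance on each axis. On the first component, with 55.3% of the variance, DUX_DOX libraries lie at 47.1 to 57.5 and the other 9 at -23.2 to -13.2, and on the second EV 1, EV 3 and EV_DOX 1 lie at -21.0, -25.6 and -29.4 against -4.78 to 18.4 for the other 9.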

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

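In this part, the test of a lower share of fibre RNA was chosen after the result was seen, and the test of the scaling was planned.

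The genes here stand out because the Dux effect, DUX_DOX against EV_DOX, differed from that on normal chow, DUX against EV, by the edgeR interaction test at a Benjamini-Hochberg adjusted p under 0.05. This held for 25 of the 46 genes named for the main comparison, against 1326 of all 12751 genes. Most of the 46 were picked by their change in DUX_DOX against EV_DOX, a part of the interaction, so a high share was built in. Each value is the difference of the log2 effects. In the stress and p53 lists the differences were 7.26 for Hspa1a, 5.26 for Atf3, 4.22 for Hspb1, 2.75 for Ppp1r15a and 2.23 for Btg2. In the macrophage, cytokine and matrix lists they were 5.10 for Timp1, 4.23 for Ccl7, 2.12 for Cd68, 2.07 for Itgam and 1.34 for Ccl6. They were 1.22 for Mcm6 and 0.83 for Pcna among cell cycle genes, and 0.88 for Smad2 and 0.97 for Psmd11 in the myostatin and atrophy lists. Negative differences were -2.70 for Slc25a34, -0.91 for Klhl33, -0.89 for Fbxo32, -0.84 for Cpt2, -0.75 for Plin4, -0.70 for Dgat2, -0.67 for Ppargc1a, -0.65 for Igfbp5, -0.53 for Phkg1 and -0.50 for Ndufs1. The Fbxo32 difference was not called in 8 of the 12 fits that left out 1 library, with adjusted p up to 0.109 without DUX 1. RP24-351P7.8, a clone-named gene with 0 counts in most libraries outside DUX_DOX, had 12.83, a fitted value that depends on the prior count, and the call was lost without EV 2.

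The fast fibre, fatty acid oxidation and glycolysis genes had a median log2 fold change of -0.31 over 91 genes in DUX_DOX against EV_DOX. Most of the 91 were not called, and no call of these lists held with an estimated correlation. Rising genes that take up counts would lower all others alike, and genes called higher held 11.8% to 12.99% of the counts in DUX_DOX libraries against 5.32% to 5.80% in the other 9. With the other scalings the median was -0.332 (DESeq2 size factors) and -0.347 (upper-quartile factors), whereas a scaling effect was predicted to leave it above -0.1. The medians over all genes were -0.0233 and -0.0390 with these scalings, against -0.00533 here. These scalings and TMM centred the typical gene alike, so exchanging them could hardly move the list median and cannot decide on scaling. The values show that the median of these genes lay below that of all genes under each scaling. A lower share of fibre RNA would raise the markers of all other cell types alike. The median of 42 endothelial, fibro-adipogenic and smooth muscle markers lay 1.20 below that of the macrophage markers (difference -1.201). The 95% interval, -1.47 to -0.956, came from resampling genes and carries no spread between libraries. A rise of macrophage RNA alone would also give this gap, so it cannot decide on fibre share. The 42 markers had a median of 0.01 against -0.31 for the fibre genes. Scaling, a lower share of fibre RNA and a rise of macrophage RNA itself stay open as candidate explanations. A lower expression of these genes in fibres that carry induced Dux also stays open and was not tested.

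Other splits of the same libraries were fitted in the same way. For the interaction, 1326 genes were called with the real groups and at most 601 with the other 99 of 100 splits of the 12 libraries. These splits shuffled the group labels freely and ignored limbs that may share an animal. They ask whether the groups differ at all, not whether vector and chow interact, so they cannot exclude chance for the interaction. For comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real count and the highest other were 3224 and 0 for DUX_DOX against EV_DOX, 3772 and 0 for DUX_DOX against DUX, 0 and 25 for DUX against EV, and 5 and 1238 for EV_DOX against EV. The split with 1238 genes set EV 1, EV 3 and EV_DOX 1 against the other 3 libraries, which points to a structure of these samples other than the chow.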

How the results depend on the processing

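The offsets for GC content and transcript length and the fit without EV 3 and EV_DOX 1, and for gene lists the fits without single libraries, were chosen after the data were seen, and the other alternatives were planned.

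Over the named genes and the gene lists, 2891 values under the alternatives fixed beforehand kept their side of the threshold, 164 were no longer past it, 25 passed it newly and 1 reversed. Direction was compared only for values past the threshold in either fit. Of values past it in neither, 22 of 793 for named genes and 6 of 259 for lists changed sign. Under the added alternatives, over the named genes alone, 385 kept their side, 12 were lost and 2 were gained, and 7 of 121 past it in neither fit changed sign. The reversed result was the sarcomere and dystrophin list for doxycycline in Dux muscle, with a camera adjusted p of 0.899 downwards and a fry adjusted p of 0.00613 upwards. Its members moved in both directions, and the cause was not tested.

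For DUX_DOX against EV_DOX the count was 2109 to 3355 with each library left out in turn, lowest without DUX_DOX 3, against 3224, and the share of higher genes was 50.9% with upper-quartile factors against 59.1%. For DUX_DOX against DUX it was 2713 to 4158 against 3772, within 1.5 times in each alternative. For DUX against EV it was 0 to 118 with each library left out, highest without EV 2, against 0, and 115 in DESeq2. For EV_DOX against EV it was 0 to 10 against 5, with 1 under upper-quartile factors, 12 in DESeq2, 0 in limma-voom, 0 with only the groups compared (fewer libraries), 0 with the GC content offset, 2 with the transcript length offset and 0 without EV 3 and EV_DOX 1. For the interaction it was 813 (without EV 3) to 2148 (without EV_DOX 1) against 1326. The overlap of the vector effects on the 2 chows, as Pearson r across genes, was 0.129 to 0.297 with each library left out, and 0.199 without EV 3 and EV_DOX 1, against 0.244. Except where fewer libraries were fitted, the cause was not tested. No main call of DUX_DOX against EV_DOX turned its sign in any alternative, 0 of 3224.

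With an estimated correlation, which is above the preset value for most lists, 2 of 13 lists remained past the threshold for DUX_DOX against EV_DOX, 0 of 14 for DUX against EV, 0 of 5 for EV_DOX against EV, 1 of 14 for DUX_DOX against DUX and 3 of 15 for the interaction. Fry called 0 lists for DUX against EV and 0 for EV_DOX against EV. With the transcript length offset, 13 of the 13 lists of DUX_DOX against EV_DOX, 8 of the 14 of DUX against EV, 2 of the 5 of EV_DOX against EV, 14 of the 14 of DUX_DOX against DUX and 13 of the 15 of the interaction remained. Lost for the interaction were the myostatin-activin list (adjusted p = 0.0764) and the mitochondrially encoded genes (adjusted p = 0.0595).

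With each library left out in turn, lists past camera numbered 10 to 15 for DUX_DOX against EV_DOX, 9 to 14 for DUX against EV, 2 to 9 for EV_DOX against EV, 14 to 15 for DUX_DOX against DUX and 14 to 17 for the interaction, and without EV 3 and EV_DOX 1 they numbered 14, 10, 6, 15 and 17. Over all these fits together, 7 calls were lost for DUX_DOX against EV_DOX, from 13 lists past camera with all libraries. For DUX against EV 23 were lost from 14 lists, for EV_DOX against EV 18 from 5 and for the interaction 4 from 15. Each such list could be lost once per fit. The 390 values per comparison also hold lists not past camera, which could not be lost. For EV_DOX against EV, 4 lists reversed without EV_DOX 3, and the cause was not tested. They were oxidative phosphorylation (adjusted p = 0.161, from 3.43e-07 to 0.663 over the fits), fatty acid oxidation (0.00488, up to 0.993), matrix (0.00986, from 6.20e-05 to 0.898) and fibro-adipogenic genes (0.0270, up to 0.907).

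The libraries showed no clear pairing by replicate number, which does not rule pairing out. Deviations of libraries with the same number from their group means had correlations of -0.105, 0.176 and 0.117 between the vectors on normal chow, -0.112, 0.0943 and 0.00476 on doxycycline chow, 0.204, 0.126 and -0.419 between the chows in empty vector muscle and 0.0244, -0.0497 and 0.0596 in Dux muscle, and not every library correlated best with its own number. With the number as a block the counts were 2817 for DUX_DOX against EV_DOX, 0 for DUX against EV, 0 for EV_DOX against EV, 3626 for DUX_DOX against DUX and 1007 for the interaction, and camera with the block called 3 lists for EV_DOX against EV, without oxidative phosphorylation and antigen presentation (adjusted p = 0.0562 each). For DUX against EV the macrophage list was lost with the block (adjusted p = 0.0718) and the interferon list was gained (adjusted p = 0.00856, upwards), and list calls in the other comparisons stayed the same.

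Depth of 11880593 to 13811999 counts per library limits what can be said of genes with few counts. Bounds such as at least 815-fold for Usp17le follow from the floor of 3 counts. In the simulations small changes were often missed, with 37.3% of 1.5-fold changes recovered for DUX_DOX against EV_DOX and 10.4% for the interaction. The simulations changed 66 or 67 genes per fold, against 3224 genes called in the real comparison. Adjustment is stricter where fewer genes change, so these shares need not hold for the real data. The median absolute log2 fold change of the 3224 calls was 0.567.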

Other observations

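In this part, the tests of a length bias between libraries and of reads carried over, and the genes of the next paragraph, were chosen after the result was seen. The GC content offset used here was added after the data were seen.

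Lists that did not pass camera held genes with large changes in DUX_DOX against EV_DOX in edgeR. In the sarcomere scaffold and dystrophin list, with 10 higher and 12 lower of 32 genes (camera adjusted p = 0.688), Ankrd1, a titin-associated repressor, rose by 5.74 (SE 0.35), Xirp1, an actin-binding protein of damaged sarcomeres, by 4.27 (SE 0.17), Cryab, a small heat shock protein of the Z-disc, by 3.59 (SE 0.17) and Flnc, an actin crosslinker, by 2.97 (SE 0.19). Csrp3, a Z-disc stress sensor of the slow-twitch list, rose by 5.59 (SE 0.45). In the sarcomere and dystrophin list Ttn fell by 0.39 (SE 0.12), Neb by 0.38 (SE 0.11, adjusted p = 0.0240) and Dmd by 0.37 (SE 0.10, adjusted p = 0.0146). In the denervation list Runx1 rose by 1.96 (SE 0.26), Gdnf by 1.83 (SE 0.32) and Musk, the receptor kinase of the neuromuscular junction, by 1.45 (SE 0.22), whereas Chrna1, a subunit of the acetylcholine receptor, had a log2 fold change of -0.02 (adjusted p = 0.953). Myog, a myogenic transcription factor, rose by 1.11 (SE 0.17). Further genes of the myostatin-activin list went both ways. Fstl1 and Fstl3, of the follistatin-like family, rose by 1.01 (SE 0.26) and 1.09 (SE 0.32), and Wfikkn2, a myostatin-binding inhibitor, fell by 0.68 (SE 0.12) and Acvr1b, a type I activin receptor, by 0.53 (SE 0.14).

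Fold changes against the EV libraries followed transcript length, with a Spearman rho across genes of -0.430 for DUX against EV, -0.378 for EV_DOX against EV, -0.0603 for DUX_DOX against EV_DOX and 0.0159 for DUX_DOX against DUX. Fmod stood at 540 CPM in EV 3 and 499.6 CPM in EV_DOX 1 against at most 121 CPM elsewhere. Tendon tissue in the muscle would dilute all fibre genes alike, yet within 195 fibre genes the rho was -0.4851. This argues against tendon as the whole cause. The 95% interval of the rho, -0.596 to -0.354, came from resampling genes and carries no spread between libraries. GC content is argued against by a rho of -0.4 that remained under the GC offset. A length bias between libraries stays a candidate explanation only in part, since the trend of single libraries varied within EV_DOX by 0.5282, above the 0.428 between the means of EV and DUX, but by 0.279 within EV, 0.123 within DUX and 0.330 within DUX_DOX, below it. An effect of the Dux vector on long genes was not tested and stays open as a part of the cause, since EV libraries (0.103 to 0.382) did not overlap DUX libraries (-0.221 to -0.0978), but EV_DOX 2 (-0.117) and EV_DOX 3 (-0.259), which carry no Dux, lay within and below the range of DUX.

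Dux target genes had traces of reads in Dux muscle on normal chow. Over 14 target genes below 1 CPM in the empty vector libraries, a selection made after the counts were seen, there were 15 counts in DUX and 8 in EV and EV_DOX together, a ratio of 3.59 (95% counting interval 1.43 to 9.79, exact permutation p = 0.0238, one-sided, over 84 permutations of 9 libraries). In the selection made at first, which left out Tmem92, there were 7 and 4 counts, a ratio of 3.36 (0.853 to 15.6). The 15 counts were spread over the genes in the proportions of the DUX_DOX libraries within sampling noise (simulated chi-square p = 0.5538). Leaky expression of Dux without doxycycline and reads carried over from the induced libraries cannot be told apart, since both predict these proportions and 15 counts are few.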
